A study of Mus musculus with 6 samples.

How the data were processed

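Poly-A selected, stranded, paired-end RNA sequencing libraries were made from dorsal root ganglia of 8-week-old C57BL6J mice, per the labels' protocols. The 6 libraries were 3 control pools and 3 prenatal stress pools, and each was a pool of 3 mice. Dams of the stress group were restrained in tubes under a bright light 3 times a day for 30 min each time, and control dams were left undisturbed. The protocol label gives E13 to E18 for the stress and the series design gives E13.5 to E18.5. The protocol label also gives 3 mice per group where the series design gives 9. Libraries were made from 3000 ng of RNA with integrity numbers of 8.2 to 8.6 and 11 PCR cycles, per the labels' protocols. The labels give no litter, cage or library batch and no sex for a pool. The names of the 6 files carry 1 flow cell lane. Because litters are not given, p-values measure the spread between pools and not the spread between litters.

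The deposited values were raw counts of reads per gene symbol, with 1 file per library, and were used without any change by the authors' normalization. FastQC, STAR 2.4 and HTSeq 0.9.1 are named in the submitters' processing notes, together with the builds GRCm39 and mm10. Which build was used, and the strand setting of the counter, are not given in the sources used here, so antisense and overlapping genes could share reads and no coordinates are printed. Reads that HTSeq gave to no gene made up 15.3% to 16.2% of each file and were left out of library sizes and tests. The files held 55809 gene symbols, of which 50664 were symbols of GENCODE M21. That annotation was used only for symbols, for the GC content and length of each gene's longest transcript, and for matches to pseudogene transcripts (minimap2 2.31-r1302, at least 90% identity over 200 bases). A GC content and length were found for 95.2% of the genes tested.

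Total gene counts in M were 69.0, 65.0 and 87.4 in control pools 1 to 3 and 77.6, 65.9 and 51.7 in prenatal stress pools 1 to 3. Counting error is therefore small for a gene at 10 CPM, and the number of pools limits the precision. No pair of libraries agreed within sampling noise: the chi-square per degree of freedom ranged from 10.98 to 36.41 over the 15 pairs, so each library was counted as a replicate.

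Genes were tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM factors, filterByExpr (minimum count 10) and the quasi-likelihood F test of prenatal stress against control. The Benjamini-Hochberg adjusted p had to be under 0.05 over the 20146 genes that passed the filter. The standard error of a log2 fold change was its size divided by the square root of F. Levels are CPM with TMM factors, given as mean ± SD over 3 pools. The genes that report sex and the keratins are given as CPM with TMM factors computed before the low-count filter. Gene lists were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 33 lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. Each gene's p was also adjusted over its list alone.

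The lists, their members, the tests, the other ways of running them and the rule for named genes were fixed before the data were examined. The lists held markers of itch receptors and pruriceptors, peptidergic and nonpeptidergic nociceptors, C low-threshold mechanoreceptors, myelinated sensory neurons and all neurons. They also held mechanosensitive channels, excitability channels, satellite glia, myelinating Schwann cells, macrophages, mast cells, lymphocytes, neutrophils and marrow, erythroid cells, endothelial and mural cells. Skeletal muscle, adipocyte, fibroblast and matrix, central nervous system, and bone and cartilage markers covered neighbouring tissue. The remaining lists were cholesterol synthesis, glucocorticoid response, immediate early genes, nerve injury, interferon response, antigen presentation and complement, circadian genes, heat shock, the mitochondrial genome, the nuclear respiratory chain and ribosomal proteins. Named genes were up to 10 higher and 10 lower genes with the largest fold among those that passed the test, had a mean of at least 1 CPM and did not overlap between groups, without clone or predicted names. The rule added up to 3 members of smallest p per list, any list member that passed, all itch and mechanosensitive channel genes, and the genes that report sex. The nerve injury genes Gap43, Flrt3, Ecel1, Csf1, Stmn4, Sox11, Jun and Cck are named below but are outside the rule. So are Apoe, Usp18, Atp5b, Cox4i1, Cox7a2, Fos, Junb, Fkbp5, Acta1, Hbb-bs and the keratins. Other genes outside the rule are said to be so where they are named. Not every gene that the rule takes is reported here.

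The labels give the same replicate numbers 1 to 3 in both groups and do not say what a number stands for. Across genes, the deviations from the group means of same-numbered pools correlated at 0.34, 0.22 and 0.13, and those of pools with different numbers at -0.30 to 0.12. By a rule set in advance (each pair above 0.1) the numbers were taken to pair the pools, from the data alone. A fit with the replicate number as a block was set beside the main one, which used no pairing. The evidence for pairs is weak, since control pool 3 and stress pool 2 correlated at 0.12, near the 0.13 of the 2 pools numbered 3. Pools 1 were both low in the central nervous system list (means -2.07 and -1.46) and pools 2 both high (1.74 and 1.62). Whether spinal cord content made their correlations was not tested. The alternatives were DESeq2 1.42.0 size factors, upper-quartile factors, no low-count filter, a mean of at least 1 CPM, the block, and sex genes as a covariate. Others were limma voom with and without library quality weights, the DESeq2 Wald test, an adjusted p under 0.10, mitochondrial and the 10 most abundant genes left out, a prior count of 0.5, and each pool left out in turn. A per-library correction for GC content and length (splines of 5 df), its combination with the block, and edgeR with a robust estimate of the spread were chosen after seeing the data.

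The scripts were tested on simulated counts for the 3 against 3 comparison, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. Over 19853 simulated genes, edgeR recovered 67.2% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 100% of those changed 4-fold, with 18 false calls among 185. DESeq2 recovered 82.1%, 89.6% and 100% at those folds, with 53 false calls among 234. With the block, 65.7%, 80.6% and 100% were recovered, with 33 false calls among 197. Camera called the 1 list shifted in the simulation and 0 of the other lists, and the GC correction lowered the calls made by a simulated GC trend from 24 to 0. No trend with length was simulated, so the length part of the correction was not tested in this way. The simulated genes were drawn independently of each other, so the simulation could not show false list calls that come from correlated members. In the data the estimated correlation was 0.729 for the interferon list, 0.677 for the C low-threshold list and 0.0465 for the nerve injury list.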

Results

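Transcripts were measured in dorsal root ganglia, which hold the cell bodies of sensory neurons together with their glia, from 8-week-old offspring of stressed or undisturbed dams. There were 3 control pools and 3 prenatal stress pools, each of 3 mice, with 51.7 to 87.4 M gene counts per pool. The single comparison asked which transcripts of the adult ganglion differed after stress of the dam in late gestation. Single genes were tested with edgeR's quasi-likelihood test and lists with camera, both with Benjamini-Hochberg adjustment, and each adjusted p comes from these unless another test is named. Xist, the transcript of the inactive X chromosome, had 9 to 19 counts in each pool. The Y-linked gene Ddx3y stood at 77.5 to 81.2 CPM, Eif2s3y at 43 to 54.8 CPM, Kdm5d at 21.5 to 23.9 CPM and Uty at 27.9 to 34.5 CPM in all 6 pools, while the labels state that both sexes were used. These values argue against a sizeable share of female RNA in any pool, so the results may not cover females.

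Of 14 tested genes that sensory neurons switch on after nerve injury, 4 fell in the prenatal stress pools and 12 had negative values, and the list was called lower with a preset correlation (camera adjusted p = 9.85e-11; adjusted p = 0.14 with an estimated correlation). Sprr1a, a small proline-rich protein induced in axotomised neurons, fell from 9.1 ± 0.972 CPM in controls to 0.523 ± 0.34 CPM (SD, n = 3 pools each; log2 fold change -4.10 ± 0.38 SE, adjusted p = 0.015). Atf3, a stress-induced transcription factor used as a marker of injured neurons, fell from 27.4 ± 3.96 to 12.7 ± 1.84 CPM (-1.12 ± 0.13, adjusted p = 0.0443). Gpr151, an orphan receptor, fell from 3.91 ± 0.346 to 1.45 ± 0.123 CPM (-1.43 ± 0.13, adjusted p = 0.0147), and the neuropeptide galanin (Gal) from 23.8 ± 1.23 to 16.4 ± 0.411 CPM (-0.54 ± 0.05, adjusted p = 0.02).
Adjusted over the list alone, 10 members were lower. The 6 added there were Gap43 (-0.25), Flrt3 (-0.38), Ecel1 (-2.06), Csf1 (-0.27), Stmn4 (-0.51) and Sox11 (-0.41), while Jun, another injury-induced factor, stood at 0.09 ± 0.04 and the neuropeptide Cck at 0.88 ± 0.85. The list had a median log2 fold change of -0.46. Fry, which asks whether the members move 1 way without comparing them with other genes, gave an adjusted p of 0.0113. The mean of the list was above its average in the 3 control pools (0.37, 0.43 and 0.53 on the log2 scale) and below it in the 3 stress pools (-0.65, -0.06 and -0.63).

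Other genes outside that list were lower too. The neuropeptide neurotensin (Nts) fell from 23 ± 3.65 to 9.87 ± 1.22 CPM (-1.22 ± 0.13, adjusted p = 0.0297). The laminin receptor subunit Itga7 fell from 253 ± 11.5 to 199 ± 4.6 CPM (-0.35 ± 0.04, adjusted p = 0.0404), and galectin-1 (Lgals1) from 179 ± 2.27 to 146 ± 1.02 CPM (-0.29 ± 0.03, adjusted p = 0.0156). The remaining 2 lower genes were outside the rule and were named after their values were seen: the growth factor Fgf3 (0.856 to 0.125 CPM, -2.77 ± 0.31, adjusted p = 0.0381) and the predicted gene Gm29374 (1.09 to 0.132 CPM, -3.06 ± 0.25, adjusted p = 0.00977).
Gal, Itga7, Lgals1 and Fgf3 lost their call with the replicate number as a block (adjusted p = 0.0696, 0.0726, 0.0726 and 0.091). Over their 20 alternatives the adjusted p ranged from 1.19e-11 to 0.174 for Gal, 3.54e-12 to 0.186 for Itga7, 2.44e-17 to 0.174 for Lgals1 and 0.0023 to 0.174 for Fgf3. Sprr1a lost its call without control pool 1, control pool 2 or stress pool 1 (adjusted p = 0.0663, 0.0768 and 0.107) and with a robust spread (0.0613; range 3.98e-39 to 0.107).
In the order control pools 1 to 3 and stress pools 1 to 3 left out, Atf3 had an adjusted p of 0.182, 0.0768, 0.115, 0.277, 0.167 and 0.0698. Gal had 0.0967, 0.0713, 0.0872, 0.174, 0.0737 and 0.0893. Itga7 had 0.182, 0.0768, 0.135, 0.186, 0.171 and 0.12. Lgals1 had 0.0967, 0.125, 0.0804, 0.174, 0.0719 and 0.064. Fgf3 had 0.147, 0.125, 0.131, 0.174, 0.0627 and 0.123. Gm29374 lost its call without control pool 2 (0.0713), stress pool 1 (0.0515) or stress pool 2 (0.0534). Gpr151 and Nts kept their call without control pool 1. Without control pools 2 and 3 and stress pools 1 to 3, Gpr151 had 0.0768, 0.0511, 0.0682, 0.0627 and 0.0698 and Nts had 0.0768, 0.0872, 0.174, 0.0627 and 0.0995.

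The genes that rose had small folds and little spread between pools. Ccdc85b, a coiled-coil transcriptional repressor, rose from 17.9 ± 0.136 to 33 ± 0.468 CPM (log2 fold change 0.89 ± 0.04, adjusted p = 0.000721). Pcsk1n, an inhibitor of a prohormone convertase, rose from 43.8 ± 3.01 to 80.6 ± 6.83 CPM (0.88 ± 0.07, adjusted p = 0.0113). Jund, a member of the AP-1 family, rose from 20.2 ± 0.317 to 33.4 ± 1.71 CPM (0.73 ± 0.05, adjusted p = 0.00541), and Cox8a, a subunit of cytochrome c oxidase, from 85.9 ± 3.77 to 136 ± 1.36 CPM (0.66 ± 0.04, adjusted p = 0.00365).
The tubulin polyglutamylase subunit Tpgs1 (0.73 ± 0.07), the ribonuclease Trir (0.71 ± 0.05), the Myc relative Bmyc (0.66 ± 0.05) and the homeobox factor Tlx2 (0.58 ± 0.05) also rose, with adjusted p from 0.00687 to 0.0156. The mitochondrial protein gene Chchd2 (0.85 ± 0.10, adjusted p = 0.0381) and the ribosomal protein gene Rpl13 (0.58 ± 0.04, adjusted p = 0.00541) rose as well, but both match pseudogene transcripts that could share their reads. The other 7 higher genes, named after their values were seen, were Gm1673, Mpc2, Ndufab1, Gadd45gip1, Cox6a1, Isl2 and Clta, at log2 fold changes of 0.24 to 1.13; Ndufab1 also matches a pseudogene transcript. With the replicate block 4 of these 7 lost their call: Gm1673 (adjusted p = 0.0988), Gadd45gip1 (0.111), Isl2 (0.111) and Clta (0.117).
Ccdc85b and Cox8a kept their call in all 20 alternatives. A correction for GC content and length ended the calls of Tpgs1 (0.58, adjusted p = 0.0581, range over 20 alternatives 2.41e-16 to 0.135) and Tlx2 (0.33, adjusted p = 0.125, range 4.02e-14 to 0.125). It also ended those of Gm1673 (0.87, adjusted p = 0.0874, range 1.99e-08 to 0.3), Cox6a1 (0.31, adjusted p = 0.07, range 6.19e-15 to 0.174) and Isl2 (0.25, adjusted p = 0.232, range 6.01e-09 to 0.342). Jund kept its call with that correction, but its log2 fold change shrank from 0.73 to 0.49 (edgeR adjusted p = 0.0094).
Without control pool 2 the other 8 named genes lost their call: Pcsk1n (0.0768), Chchd2 (0.247), Tpgs1 (0.121), Jund (0.0713), Trir (0.0713), Bmyc (0.0725), Tlx2 (0.0768) and Rpl13 (0.0713). Without stress pool 1 the calls of Pcsk1n (0.0683), Chchd2 (0.174), Tpgs1 (0.135), Trir (0.0682), Bmyc (0.0871) and Tlx2 (0.0978) were lost. Without stress pool 2 those of Chchd2 (0.146), Tpgs1 (0.0737), Bmyc (0.0531) and Tlx2 (0.0602) were lost, and without stress pool 3 those of Chchd2 (0.111) and Tpgs1 (0.0698). Tlx2 also lost its call without control pool 1 (0.0689) or control pool 3 (0.057).
Of the 7 genes named after their values were seen, 5 lost their call without any 1 of the pools. In the order control pools 1 to 3 and stress pools 1 to 3 left out, Gm1673 had an adjusted p of 0.174, 0.3, 0.106, 0.181, 0.15 and 0.0995. Mpc2 had 0.14, 0.22, 0.0804, 0.174, 0.0719 and 0.0698, and Gadd45gip1 had 0.182, 0.309, 0.135, 0.277, 0.159 and 0.111. Isl2 had 0.174, 0.311, 0.194, 0.342, 0.146 and 0.123, and Clta had 0.188, 0.311, 0.191, 0.277, 0.162 and 0.0995. Cox6a1 lost its call without control pool 1 (0.0759), control pool 2 (0.173), stress pool 1 (0.174), stress pool 2 (0.0737) or stress pool 3 (0.0755). Ndufab1 lost its call without control pool 1 (0.0799), control pool 2 (0.125), stress pool 1 (0.137) or stress pool 3 (0.0698).

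**Figure D1:**
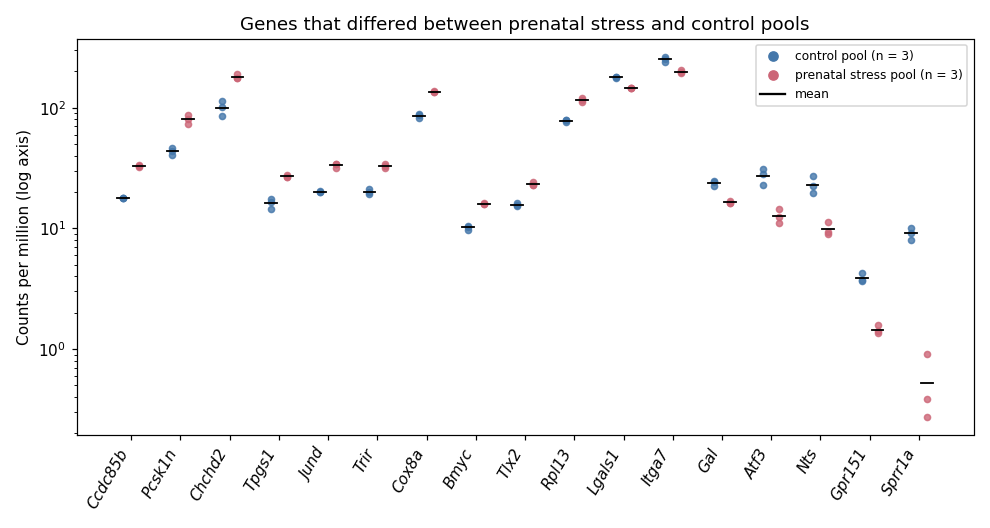
CPM (log axis) of the 17 named genes that passed the test, with 1 point per pool (blue, 3 control pools; red, 3 prenatal stress pools) and a bar at each mean. The groups do not overlap for any of the 17, which the rule for named genes required. Sprr1a has the largest difference, with 8.07 to 10 CPM in controls and 0.271 to 0.91 CPM in stress pools.

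In all, 26 of 20146 genes passed the edgeR test, 17 higher and 9 lower in prenatal stress pools, and all 26 separated the 3 stress pools from the 3 control pools. At an unadjusted p under 0.05 there were 1211 higher and 1030 lower genes. The groups did not overlap for 3645 genes (18.1%). Chance gives 10% if all pools are exchangeable, which leaves out the pairing by replicate number. The count was 14 without control pool 1, 2 without control pool 2, 13 without control pool 3, 4 without stress pool 1, 10 without stress pool 2 and 10 without stress pool 3. It was 330 (158 higher, 172 lower) with the DESeq2 Wald test, with 24 genes shared, and 49 without the low-count filter.

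Among sensory neuron classes, markers of nonpeptidergic nociceptors, C low-threshold mechanoreceptors and myelinated neurons leaned higher and those of peptidergic nociceptors leaned lower, by small amounts. Of 11 nonpeptidergic markers, 10 had positive values, among them the receptor Mrgprd at 150 ± 5.18 and 181 ± 18.2 CPM (0.27 ± 0.07) and Lpar3 (0.24 ± 0.08). The list median was 0.15 and 0 members passed over all genes or adjusted over the list alone (camera adjusted p = 0.000933; adjusted p = 0.535 with an estimated correlation). Of 7 C low-threshold mechanoreceptor markers, tyrosine hydroxylase (Th, 0.32 ± 0.07) and the purinergic receptor P2ry1 (0.27 ± 0.07) were higher adjusted over the list alone and 0 over all genes (median 0.15, camera adjusted p = 0.0345; adjusted p = 0.747 with an estimated correlation). Of 17 myelinated neuron markers, 13 had positive values, such as Ntrk3 (0.22 ± 0.06), and 0 passed over all genes or adjusted over the list alone (median 0.09, camera adjusted p = 0.0205; adjusted p = 0.523 with an estimated correlation). Of 11 peptidergic markers, the heat-gated channel Trpv1 (-0.19 ± 0.04), the peptide precursor Calca (-0.22 ± 0.06) and the substance P precursor Tac1 (-0.17 ± 0.05) were lower adjusted over the list alone and 0 over all genes (median -0.15, camera adjusted p = 0.00301; adjusted p = 0.387 with an estimated correlation).
The C low-threshold list lost its call without control pool 2 (0.119), control pool 3 (0.0529), stress pool 1 (0.113) or stress pool 3 (0.249, median 0.07) and with a GC and length correction (0.0561). The myelinated list lost it without control pool 2 (0.129) or stress pool 1 (0.106) and with that correction (0.332, median 0.03), and its median was 0.14 without control pool 1.

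Markers of all neurons were close to level, with 8 of 15 positive and a median of 0.02 (camera adjusted p = 0.788). Adjusted over the list alone, the homeobox factor Tlx3 (0.44 ± 0.08) was higher and the tubulin Tubb3 (-0.18 ± 0.05) lower, and 0 passed over all genes. Of 20 excitability channels, 15 had positive values, among them the sodium channel Scn11a (0.15 ± 0.05) and the calcium channel Cacna1h (0.19 ± 0.06). Neither count of passing members was above 0, and the median was 0.11 (camera adjusted p = 0.069; 0.0359 with the replicate block; 0.758 with an estimated correlation). Of 14 mechanosensitive channels, 0 passed over all genes or adjusted over the list alone and 1 had an unadjusted p under 0.05 (median -0.01, camera adjusted p = 0.887): Piezo2, the main touch channel, stood at 455 ± 14.2 and 510 ± 37.9 CPM (0.17 ± 0.06, adjusted p = 0.378). Piezo1 stood at -0.02 ± 0.08 and Trpv4 at -0.04 ± 0.13.

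The itch list did not shift as a whole (16 tested, median -0.00, camera adjusted p = 0.283). Neurotensin (Nts), a peptide of 1 pruriceptor class, was its only member that passed over all genes. Adjusted over the list alone 4 members passed: Nts, the cytokine receptor chain Il4ra (-0.23 ± 0.05) and the sphingosine phosphate receptor S1pr3 (-0.14 ± 0.04) were lower, and the cytokine receptor Crlf2 was higher (0.45 ± 0.11). Receptors that define pruriceptors had values near 0, with Mrgpra3 at -0.01 ± 0.09, Mrgprx1 at 0.02 ± 0.05 and Il31ra at -0.00 ± 0.10. The natriuretic peptide Nppb stood at -0.15 ± 0.11 and somatostatin (Sst) at 0.28 ± 0.20.

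Markers of satellite glia, the cells that wrap sensory neuron bodies, were lower as a list, while those of myelinating Schwann cells did not pass. Adjusted over the list alone, Fabp7 (152 ± 14 to 104 ± 18.3 CPM, -0.55 ± 0.13), Lgi4 (-0.20 ± 0.05), Ednrb (-0.20 ± 0.05) and Apoe (-0.16 ± 0.05) were lower among 10 markers, and 0 passed over all genes (median -0.17, camera adjusted p = 0.00324; adjusted p = 0.535 with an estimated correlation). The satellite glia list lost its call without stress pool 3 (0.0586, median -0.09), and its median was -0.11 without control pool 2. Stress pool 3 had the lowest list mean for satellite glia (-0.18) and for Schwann cells (-0.26). Control pool 2 had the highest for satellite glia (0.17) and for the central nervous system list (1.74), while stress pool 2 stood at -0.02 and 1.62. Of 15 Schwann cell markers 12 had negative values, with a median of -0.06 (camera adjusted p = 0.224), and Ncmap stood at -0.23 ± 0.07.

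Interferon-induced genes had negative values for 16 of 16 members. Adjusted over the list alone, Oasl2 (60.3 ± 3.87 to 45.3 ± 5.7 CPM, -0.42 ± 0.09), Ifit1 (-0.78 ± 0.22), Bst2 (-0.38 ± 0.11) and Usp18 (-0.76 ± 0.23) were lower, and 0 passed over all genes (median -0.33, camera adjusted p = 1.07e-05; adjusted p = 0.636 with an estimated correlation). The median was -0.19 without control pool 3, -0.21 without stress pool 1 and -0.52 without stress pool 3. The list mean was 0.43 in control pool 3 and 0.18 in stress pool 3, against 0.06 and 0.07 in the other control pools and -0.43 and -0.31 in the other stress pools. The neutrophil and marrow list was also highest in control pool 3 (0.77) and stress pool 3 (1.24) and lowest in stress pool 1 (-1.96). It differed in stress pool 2, where it stood at 0.29 and the interferon list at -0.31. Of 12 antigen presentation and complement genes, C4b (-0.28 ± 0.04), B2m (-0.28 ± 0.06) and Psmb8 (-0.32 ± 0.09) were lower adjusted over the list alone and 0 over all genes (median -0.14, camera adjusted p = 0.00239; adjusted p = 0.636 with an estimated correlation; without stress pool 1, median -0.03 and 0.113; with library quality weights, median -0.22). Immune cell markers did not pass, with macrophages at a median of -0.05 (17 tested, camera adjusted p = 0.289), mast cells at -0.05 (10 tested, 0.283) and lymphocytes at 0.13 (10 tested, 0.896, with a negative camera direction). Stress pool 1 had the lowest list mean for antigen presentation and complement (-0.22), and also for macrophages (-0.29) and lymphocytes (-0.87). Whether immune cell content contributed to the lower lists was not tested. The mast cell protease Cpa3 stood at 1.67 ± 0.112 and 1.36 ± 0.111 CPM (-0.30 ± 0.14, adjusted p = 0.471), and 0 of the 10 mast cell markers had an unadjusted p under 0.05.

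Cholesterol synthesis genes had small negative values for 17 of 18 members, such as the decarboxylase Mvd (-0.17 ± 0.04). None passed over all genes or adjusted over the list alone (5 had an unadjusted p under 0.05), with a median of -0.08 (camera adjusted p = 3.78e-05; adjusted p = 0.262 with an estimated correlation). Ribosomal protein genes had negative values for 24 of 27 members while Rpl13 rose, the only one to pass by either adjustment (median -0.06, camera adjusted p = 0.000288; adjusted p = 0.535 with an estimated correlation; 0.0835 with a GC and length correction). Control means of the mitochondrial genome transcripts ranged from 2.69 to 9700 CPM. Whether reads of the low members were lost in counting was not tested, so these may be poor measures. The mitochondrial list had a median of -0.10, with mt-Nd2 at -0.21 ± 0.07 and 0 of 13 passing by either adjustment (camera adjusted p = 0.0275; adjusted p = 0.758 with an estimated correlation). That call was lost without control pool 3 (0.367, median -0.05), stress pool 1 (0.102) or stress pool 2 (0.173) and with the correction (0.0507). Of 21 nuclear respiratory chain genes, Cox8a rose, and adjusted over the list alone Cox5a (0.21 ± 0.05) and Atp5b (0.11 ± 0.03) were also higher and Ndufa1 (-0.14 ± 0.03), Cox4i1 (-0.12 ± 0.04) and Cox7a2 (-0.12 ± 0.04) lower (median -0.05, camera adjusted p = 0.106).

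Of 14 immediate early genes, Atf3 fell, and adjusted over the list alone Nr4a1 (-0.38 ± 0.09) was lower too (median -0.14, camera adjusted p = 0.00469; adjusted p = 0.387 with an estimated correlation). The median was -0.25 without stress pool 2 and -0.24 without stress pool 3. Fos stood at -0.49 ± 0.21 and Junb at 0.26 ± 0.11. Genes that glucocorticoids induce did not pass as a list (15 tested, median -0.09, camera adjusted p = 0.283), and the sensitive reporter Fkbp5 stood at 0.03 ± 0.07. Circadian genes had a median of 0.14 (15 tested, camera adjusted p = 0.0622), with the repressor Nr1d2 at 0.15 ± 0.03 higher adjusted over the list alone. Heat shock genes had a median of -0.03 and a mean of 0.03 (12 tested, camera adjusted p = 0.706), with the inducible chaperone Hspa1b (0.47 ± 0.11) higher adjusted over the list alone.
Camera called 12 of the 33 lists, 9 lower and 3 higher. With an estimated correlation 0 lists passed and 4 had an unadjusted p under 0.05, and fry called 1.

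**Figure D2:**
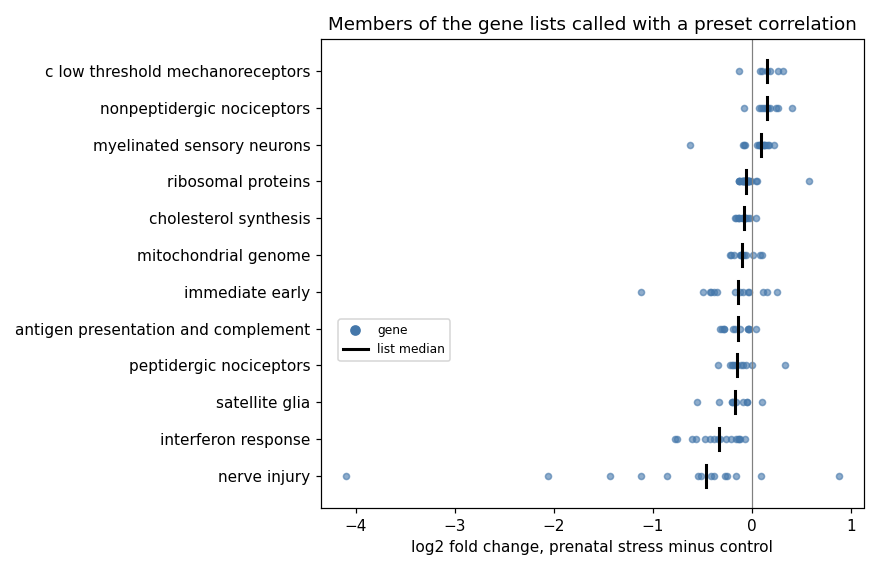
Log2 fold change of prenatal stress against control for each member (blue points) of the 12 lists called with a preset correlation, with the list median as a black bar. The nerve injury list has the lowest median (-0.46), and Sprr1a at -4.10 is its lowest member.

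Transcripts of muscle, spinal cord, blood and marrow differed between pools of the same group. Skeletal muscle markers were high in control pool 3, where the muscle actin Acta1 was at 512 CPM against 3.19 to 10.7 CPM elsewhere, and the list mean stood 4.90 above its average (median over 14 genes -3.99, camera adjusted p = 0.0745). Spinal cord transcripts such as the glycine transporter Slc6a5 were at 25 CPM in control pool 2, 14 CPM in stress pool 2, 6.33 CPM in control pool 3 and 0.404 to 1.34 CPM in the rest (central nervous system list, median -0.34, camera adjusted p = 0.511). The globin Hbb-bs ranged from 45.7 CPM in stress pool 1 to 288 CPM in stress pool 3 (erythroid list, median 0.61, camera adjusted p = 0.788), and neutrophil and marrow genes followed the same pools (median 0.10, negative camera direction, adjusted p = 0.447). Bone and cartilage genes had a median of -0.26 (camera adjusted p = 0.069; 0.0118 with the replicate block; 0.523 with an estimated correlation) and negative values for 9 of 10 members. Cnmd stood at -0.26 ± 0.07, without overlap between groups. Adipocyte (median -0.12, camera adjusted p = 0.586), fibroblast and matrix (0.01, 0.706), endothelial (-0.03, 0.511) and mural cell markers (-0.09, 0.586) did not pass, and 0 of their members passed by either adjustment.

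**Figure D3:**
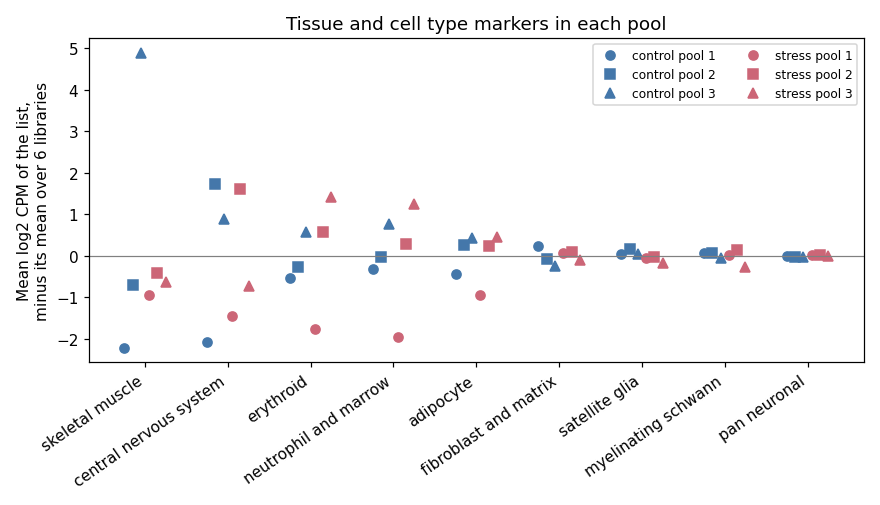
Mean log2 CPM of 9 marker lists in each pool, minus the list's mean over the 6 pools (blue, control; red, prenatal stress; the marker shape gives the pool number). Skeletal muscle stands at 4.90 in control pool 3, the central nervous system list at 1.74 in control pool 2 and 1.62 in stress pool 2, and the list for all neurons between -0.02 and 0.03.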

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

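The GC and length corrections and the robust spread were chosen after seeing the data. The 26 changed genes became 49 without a low-count filter and 330 with the DESeq2 Wald test, which left 5142 genes without an adjusted p, and 2 to 14 with a pool left out. The 17 higher genes became 158 with the DESeq2 Wald test and 2 to 11 with a pool left out. The 9 lower genes became 24 without a filter, 172 with the DESeq2 Wald test, 16 at an adjusted p under 0.10, 16 with the replicate block and the GC and length correction, and 0 to 4 with a pool left out. The counts of 0 came from edgeR without control pool 2 or stress pool 1, where 869 and 856 lower genes had an unadjusted p under 0.05. The 12 lists became 19 with library quality weights, 0 with an estimated correlation, 1 with fry and 11 to 17 with a pool left out. The causes of these shifts were not tested. Fits with a pool left out have fewer pools, but their count of changed genes also depended on which pool was left out (2 to 14).

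With the replicate block, 22 genes (14 higher, 8 lower) were called, 18 of them shared with the main test, and 14 lists; Gal, Itga7, Lgals1, Fgf3, Gm1673, Gadd45gip1, Isl2 and Clta lost their call, and it changed no other call among the 26 genes and the 12 lists. Other counts of genes were 25 with DESeq2 size factors, 27 with upper-quartile factors, 22 with a mean of at least 1 CPM, 22 with the sex covariate, 29 with voom, 32 with quality weights, 25 with the GC and length correction, 31 with that correction and the block, and 30 with a robust spread. Over the 17 genes that the rule took and that passed, 266 repeats kept the call and 74 lost it, and over the lists called 175 kept it and 41 lost it. The gene repeats include an adjusted p under 0.10, which is the main fit at a wider threshold and could end no call. Without control pool 2, 15 of the 17 genes lost their call. Calls ended with the sex covariate for Atf3 (adjusted p = 0.0828), Itga7 (0.0653), Fgf3 (0.0701) and Gm1673, Gadd45gip1, Isl2 and Clta (0.0765 each), and with the mean of 1 CPM for Atf3 (0.0531) and Isl2 (0.0531). Every pool had Y-linked transcripts and only 9 to 19 Xist counts, so the sex covariate could not test an effect of sex. That mean left Fgf3 and Gm29374 untested, and DESeq2 gave them no adjusted p. Isl2 also lost its call with DESeq2 size factors (0.0542) and upper-quartile factors (0.0718). They ended with the GC and length correction for Itga7 (0.0717) and Lgals1 (0.163), and with a robust spread for Chchd2 (0.0613) and Atf3 (0.0613). No value changed direction. Depth limits genes such as Fgf3, at under 1 CPM, more than those named above it.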

Other observations

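The test on genes that fall after axotomy, the corrections for GC content and length as alternatives, and the genes named outside the rule were chosen after the results were seen. The rule of the axotomy test was also made stricter after its value was seen, which turned its reading from favourable to undecided. The genes in the rest of this paragraph were picked after their values were seen, none passed the test, and no group was tested with them. The urokinase receptor Plaur stood at 11.9 ± 1.07 and 7.02 ± 0.645 CPM in control and stress pools (-0.76 ± 0.10, edgeR adjusted p = 0.0565), and galectin-3 (Lgals3) at 16.7 ± 0.701 and 11.5 ± 0.8 CPM (-0.55 ± 0.07, adjusted p = 0.0532). The acute-phase inhibitor Serpina3n stood at -0.33 ± 0.04 (adjusted p = 0.0605) and the neurotrophin Bdnf at -0.50 ± 0.08 (adjusted p = 0.119). Dopamine beta-hydroxylase (Dbh), an enzyme of sympathetic neurons, was at 13.4 CPM in stress pool 2 and 0.0387 to 1.93 CPM in the other pools.

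The first pattern was the lower level of nerve injury genes in prenatal stress pools. A trend with GC content or length is argued against, since the list had a median of -0.47 after the correction, from -0.46 (camera adjusted p = 5.92e-11 with a preset correlation). The 9 lower genes, of which 4 are in that list, kept a median of -1.20, from -1.22, with 7 still called. They were picked as lower in these same data, so their values are a weak test. Skin RNA in the control pools is argued against by the keratins Krt5, Krt14, Krt10 and Krt1, whose sum reached 2.73 CPM at most and was below Sprr1a (8.07 to 10 CPM) in each control pool. Injured sensory neurons in the control pools may be a candidate source. The 20 genes known to fall after axotomy had a median of 0.12. Random lists matched on expression and length had a median of -0.01 and a 95th percentile of 0.02. However, 7 of the 20 were negative, among them Calca, Tac1 and Trpv1, 0 were called by edgeR (10 had an unadjusted p under 0.05) and 16 were in lists already seen. That explanation and an effect of prenatal stress cannot be told apart for these genes, because the members went both ways and any injury would coincide with the groups.

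The second pattern was that the 17 higher genes were short and GC-rich, with a median length of 1710 bases against 3670 in lists matched on expression, and a median GC content of 58% against 49.3%. The trait was not particular to them. The lower genes had a median GC content of 54.9%, against 49.4% over all tested genes with a value, and lengths of 788 to 2299 bases apart from Itga7 at 4020. After correction the median was 0.58, from 0.66, and 12 of 17 were still called, 11 with the replicate block. That argues only weakly against a GC or length trend between libraries as the whole cause, since the 17 were picked as higher in these same data. The most GC-rich members shrank: Jund from 0.73 to 0.49, Tlx2 from 0.58 to 0.33, Gm1673 from 1.13 to 0.87, Tpgs1 from 0.73 to 0.58 and Cox6a1 from 0.37 to 0.31. For these a trend may be part of the rise. In all, 15 of 17 kept at least 0.75 of their size. Shared pseudogene reads are argued against only for the 14 of 17 with no match, and Chchd2, Rpl13 and Ndufab1 stay uncertain. In lists matched on expression the median share with a match was 11.8%, so most members of any list would lack one. The share among the 17 was above that of 71.28% of those lists. Across 10185 genes (which are not independent replicates) the fold change rose with length, with a Spearman correlation of 0.36, so the higher genes, short in the median, went against the trend. In control pools 1 to 3 a pool's deviations correlated with length at -0.37, -0.09 and -0.16, and in stress pools 1 to 3 at 0.11, 0.05 and 0.33. The length trend thus separated the groups, and its source was not tested. With the GC and length correction 4 of the called lists lost their call and 8 kept it. A library effect on the sequences of the higher genes that GC content and length do not capture, and an effect of prenatal stress, stay open and untested.

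The third pattern was the number of calls, for which the 6 pools make 10 splits into groups of 3, too few for a share under 0.05. The real split gave 26 genes and the highest other 21 (1 split, the real one, had as many), and for lists the real split gave 12 and the highest other 16 (3 splits had as many). The split with 21 genes set control pool 1, stress pool 1 and stress pool 3 against the rest. It keeps both pools of replicate number 1 on one side and both of number 2 on the other, the 2 pairs with the highest correlations (0.34 and 0.22), and parts 1 pair. The same split divides the pools by spinal cord content. The central nervous system list mean was -2.07, -1.46 and -0.72 in those 3 pools, in that order. In control pools 2 and 3 and stress pool 2 it was 1.74, 0.89 and 1.62. Whether pairing or spinal cord content made the 21 calls was not tested. The other 3 splits that part all 3 replicate pairs gave 0 genes with edgeR (342 to 722 at an unadjusted p under 0.05) and 2 to 9 lists.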
